A study of Mus musculus with 43 samples.

How the data were processed

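RNA was measured in 43 mammary tumours grown in BALB/c mice, 1 library per tumour. Per the labels' protocols, mammary fragments from p53null donors aged 8 to 10 weeks were implanted into cleared mammary fat pads of syngeneic hosts aged 3 to 4 weeks. The pads had first received a hydrogel of collagen 1 with basement membrane extract at 20%. The collagen had been kept for 10 to 14 days without (soft) or with (stiff) 500 mM L-ribose, a sugar that crosslinks collagen. Tumours were taken at a maximum diameter of 2 cm. RNA came from the flowthrough of a DNA column, was enriched for poly(A) transcripts and was copied with a modified SMART-Seq3 protocol, per the labels. Groups were read from the sample titles: 22 soft and 21 stiff. The labels give no batch, litter or donor, so p-values measure the spread between tumours as if these were independent.

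The deposited estimated counts and TPM values were made by the authors with kallisto 0.46.1 on GRCm38, and edgeR 4.6.2 and R 4.3.1 are also named, per the submitters' processing notes. Per the file headers, each file gives for every transcript its length, effective length, estimated count and TPM (length-scaled transcript abundance). The effective length, deposited by the authors in the same files, was the same for each transcript in all 43 files and was used in 1 alternative. Each file held 118489 transcripts, of which 116816 matched GENCODE M21 (GRCm38) by identifier and version. The other 1673 held 0.469% ± 0.068 of counts (SD, n = 43) and were left out. Estimated counts were summed per gene over 36047 genes and rounded to whole numbers. Kallisto shares a read among all transcripts it is compatible with, so genes with near-identical copies or shared repeats can exchange counts.

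Depth was 0.70 to 9.57 M (mega) gene counts in soft and 0.94 to 11.94 M in stiff libraries. Libraries under 2.06 M, 50% of the median, are called shallow here: 1 soft and 11 stiff. The closest pair of libraries, soft 10 and soft 13, correlated at r = 0.968 across genes in log2 CPM, and no files were identical, so each was counted as 1 replicate.

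Genes were tested with edgeR 4.0.16 in R 4.3.3 (TMM scaling, filterByExpr defaults, robust quasi-likelihood fit, stiff minus soft, no covariates), with Benjamini-Hochberg adjustment and a threshold of 0.05. This left 12086 genes. Log2 CPM values used a prior count of 2. All fold changes are stiff relative to soft. Errors of fold changes are standard errors (SE), taken as the fold change over the root of its F statistic. For each of 44 gene lists fixed in advance (589 genes), a score per tumour was the mean log2 CPM of tested members, with at least 3 members. Group means of the 42 scored lists were compared by a two-sided permutation test with 100000 resamples, adjusted over lists. The smallest p these permutations can give is 1e-05. The macrophage score was related to 9 other scores with Pearson's r and Spearman's rho, with permutation p-values adjusted over the 9.

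Genes were named by a rule: the 12 lowest p-values in each direction among called genes whose group medians moved the same way, a fixed panel of 26 genes, and up to 4 members per list described. Not every gene the rule takes is reported here. A gene called repeat-bearing had a main transcript with at least 25 different 25-mers that each occurred in the main transcripts of 20 or more tested genes. This held for 1064 of 12080 genes with a sequence, and such genes are named as uncertain. H2ax is listed under its older symbol H2afx in this annotation.

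The test was run on simulated counts for stiff minus soft with genes changed by known amounts, over the 11945 genes its filter kept. It called 78% of genes raised by 1 on the log2 scale and 50% of genes lowered by 1, all 50 genes raised by 2 and all 44 genes lowered by 2 among those kept. Of its calls, 6.5% were genes simulated without change. Genes were simulated independently of each other, so this share does not cover correlated genes or subsets of tumours. Alternatives covered scaling (RLE, upper quartile), filters, DESeq2 1.42.0, limma 3.58.1, length offsets, TPM with pseudocounts of 1 and 0.1, covariates, a surrogate variable (sva 3.50.0), set tests (camera, fry), left-out shallow libraries and each tumour left out. Alternatives chosen after seeing the data were leaving out libraries with over 5% globin counts, covariates for vessels and blood, leaving out repeat-bearing genes, a covariate for the genes around Met, and relations without shallow libraries or within groups on TPM.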

Results

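The 43 libraries compared p53null mouse mammary tumours that had grown in soft collagen (22 tumours) or in ribose-stiffened collagen (21 tumours). The series title names tissue tension, macrophages, lipid peroxidation and DNA damage, and the comparison asks which transcripts differ with the ribose stiffening of the implanted matrix. No measured stiffness was used here, so stiffness cannot be told apart from other effects of the ribose treatment. Soft libraries held 4.45 ± 1.71 M (mega) gene counts and stiff libraries 3.56 ± 3.02 M (mean ± SD). The depths of stiff libraries fell into a deep and a shallow set: 11 of 21 were under 2.06 M counts, against 1 of 22 soft libraries. Globin transcripts took 7.79% ± 14.3 of counts in soft and 1.10% ± 1.96 in stiff libraries, with a maximum of 57.3% in soft 21. The single gene Timm22 took 0.85% ± 0.68 of counts in soft and 2.02% ± 2.40 in stiff libraries, with a maximum of 10.1% in stiff 38. The source of this share was not tested. Trp53 (chromosome 11, 69580359 to 69591873, GRCm38) had counts in all 43 libraries, between 15.5 and 94 CPM (log2 fold change -0.16, SE 0.19, edgeR adjusted p = 0.575). No wild-type group was included, and counts per gene do not show which part of the transcript they cover, so this does not check the null allele.

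**Figure D1:**
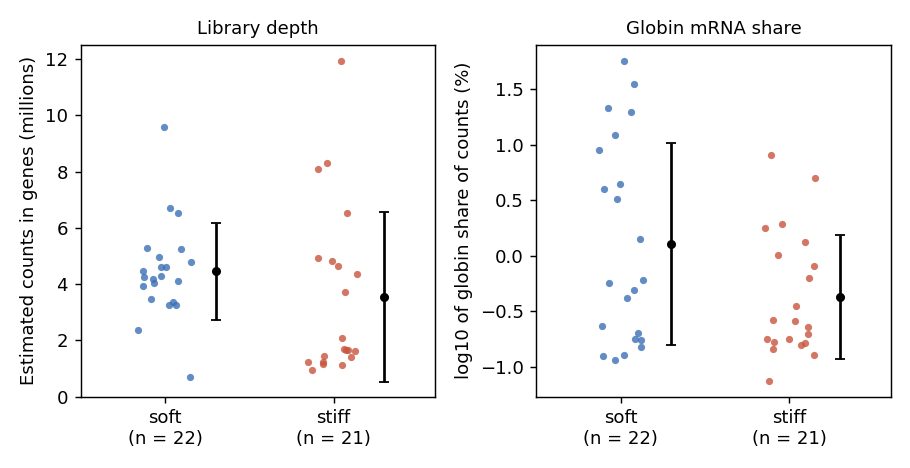
Gene counts per library in M (left) and log10 of the percentage of counts on globin genes (right) for soft and stiff tumours. Each coloured point is a library, and black points with bars are means ± SD. Of the stiff libraries 11 lie under 2.06 M counts.

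Stiff tumours differed from soft tumours in transcripts of many functions. Of 12086 genes tested, 955 were higher and 1205 lower in stiff, and 299 and 555 of these changed by more than 1 on the log2 scale. Eno3, the muscle enolase (chromosome 11, 70657202 to 70662513), rose from 3.40 ± 2.09 to 33.2 ± 61.2 CPM (SD; log2 fold change 3.28, SE 0.50, adjusted p = 0.000133). Cel, a bile salt-stimulated lipase, rose from 10.7 ± 9.48 to 47.4 ± 43.6 CPM (log2 fold change 2.20, SE 0.34). Hmga2, an architectural chromatin protein of embryonic and mesenchymal cells (chromosome 10, 120361275 to 120476469), rose from 8.45 ± 8.89 to 58.7 ± 46.5 CPM and lay above the soft median in 19 of 21 stiff tumours. S100a4, a calcium-binding protein of motile cells, rose from 37.4 ± 30.2 to 506 ± 895 CPM. Ada, which deaminates adenosine, and Cryzl1 rose by 1.05 and 1.13 on the log2 scale. Try5 rose by 2.19, but belongs to the trypsin family of close copies and is uncertain. Chrna1, Pbld1, Zan, Washc4 and Gm9894, with log2 fold changes of 3.24, 3.00, 2.18, 1.54 and 2.07, are repeat-bearing and uncertain as well.

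Among the genes lower in stiff, Creb3l2, a transcription factor of the secretory pathway (chromosome 6, 37327255 to 37442146), was 135 ± 46.1 CPM in soft and 59.1 ± 22.5 in stiff (log2 fold change -1.19, SE 0.18, adjusted p = 0.000133), and lay under the soft median in 21 of 21 stiff tumours. Hes1, a Notch target, fell by 0.97 on the log2 scale, and Arrb1, which encodes beta-arrestin 1, by 1.71. Dennd3, Fam174b, Slc46a3, Tecpr1 and Map3k6 had log2 fold changes of -1.86, -2.52, -1.36, -1.21 and -1.47. Pth1r, the parathyroid hormone receptor, and Tnrc6a, a partner of Argonaute proteins, had values of -1.93 and -0.90. Epb41, a membrane skeleton protein abundant in red cells, had a value of -2.49. Gm8956 is repeat-bearing, and its value of -2.27 is uncertain. Without the shallow libraries (21 soft, 10 stiff) 951 genes were higher and 1027 lower, of which 749 and 736 were among those above. No comparison within the shallow set was possible, since it holds 1 soft library. With adipocyte and skeletal muscle scores as covariates, 134 genes were higher and 262 lower, and Eno3, Chrna1, Zan, Gm9894, S100a4 and Epb41 were no longer called. Under upper-quartile scaling 55.2% of the calls were higher in stiff, against 44.2% with TMM and 67.4% on log2(TPM + 1). The median log2 fold change of all tested genes was -0.06.

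Basement membrane genes were lower in stiff tumours. Of 14 members, 10 fell, none rose and 4 did not pass (12 fell when adjusted over the list alone), and the score was 6.26 ± 0.65 in soft and 5.40 ± 0.68 in stiff (difference -0.86, SE 0.20, permutation p = 2e-04, adjusted p = 0.0084). The preset camera test gave an adjusted p of 1.42e-05, while adjusted p = 0.821 with an estimated correlation. Col4a1 and Col4a2, which share a promoter region and encode the main collagen 4 chains (chromosome 8, 11198423 to 11312826 and 11312805 to 11449287), fell by 1.88 (SE 0.36) and 2.06 (SE 0.40) on the log2 scale. Col4a1 was 2162 ± 1959 CPM in soft and 588 ± 431 in stiff and lay under the soft median in 20 of 21 stiff tumours. The laminin chains Lamb2 and Lamc1 fell by 0.96 and 1.28. The call of Hspg2, perlecan, was not made in 24 of 43 fits with 1 tumour left out. In the deep libraries the score difference was -1.27 (adjusted p = 0.0021). The adipocyte and muscle covariates and the covariate for the genes around Met, chosen after seeing the data, ended the call (adjusted p = 0.347 and 0.098 for the list basement membrane).

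Vessel marker genes were lower in stiff tumours, and their lists did not pass on the mean score. Of 13 endothelial genes 10 fell and 3 did not pass (12 fell adjusted over the list alone), and the score was 5.59 ± 1.69 in soft and 4.43 ± 0.98 in stiff (adjusted p = 0.077). Erg, a transcription factor of endothelium, fell by 2.24 on the log2 scale, and Tie1, Vwf and Tek by 2.19, 1.65 and 2.57. Soft tumours formed separate sets in this score: 9 lay between 6.65 and 8.01 and 13 between 3.73 and 5.33, whereas 2 of 21 stiff tumours exceeded 6. Of 11 pericyte and smooth muscle genes 7 fell (8 adjusted over the list alone), among them Notch3, Cspg4, Mcam and Pdgfrb with values of -1.86, -1.84, -2.14 and -1.68 (list adjusted p = 0.077). Camera with its preset correlation called the endothelium and pericyte lists lower (adjusted p = 7.93e-05 and 0.00345), and so did fry (0.0409 and 0.0334), while adjusted p = 0.821 for both with an estimated correlation. All 5 red blood cell genes fell (list difference -1.78, SE 0.79, adjusted p = 0.139, against 0.0431 with preset camera and adjusted p = 0.821 with an estimated correlation). Hba-a1 and Hba-a2, like Hbb-bs and Hbb-bt, are near-identical copies and uncertain individually. Without the 8 libraries over 5% globin (6 soft, 2 stiff), 955 genes were higher and 855 lower. Of these, 757 and 669 were called the same way in all libraries. The basement membrane score difference was then -0.75 (permutation adjusted p = 0.0333). That of endothelium was -0.65 (adjusted p = 0.232), against -1.16 in all libraries, and that of red blood cells -0.54 (adjusted p = 0.48). In that setting the globin calls ended, and with the vessel and blood covariates the values of Tek and the 4 globin genes turned positive, none of them called.

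**Figure D2:**
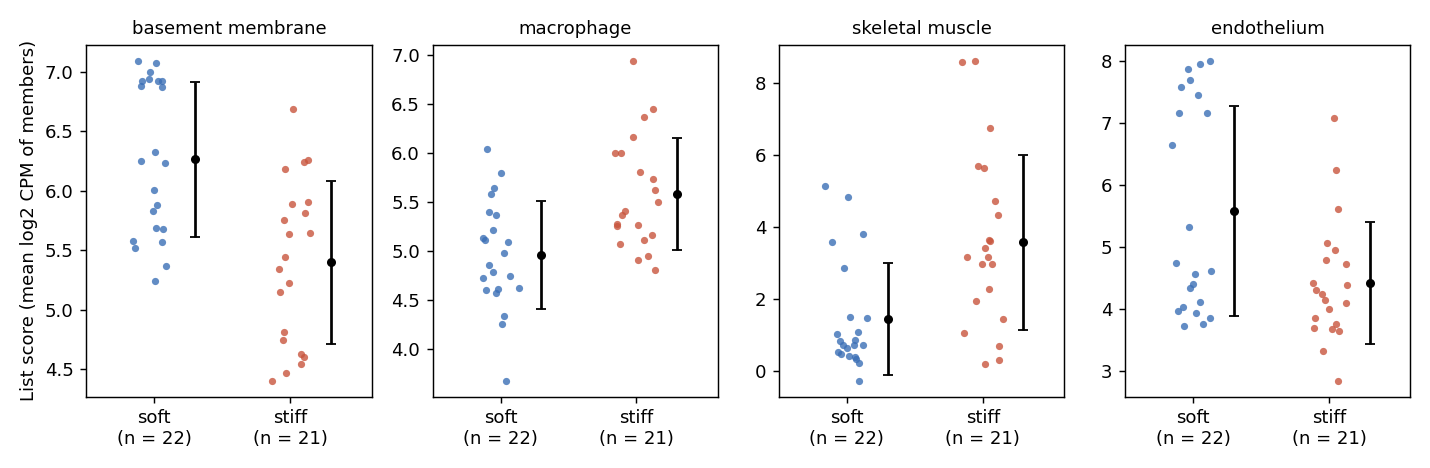
List scores (mean log2 CPM of tested members) per tumour for basement membrane, macrophage, skeletal muscle and endothelium. Each coloured point is a tumour (22 soft, 21 stiff), and black points with bars are means ± SD. Basement membrane means were 6.26 and 5.40, and macrophage means 4.96 and 5.58, in soft and stiff.

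Macrophage markers were higher in stiff tumours. Of 16 members 7 rose, none fell and 9 did not pass (7 rose adjusted over the list alone), and the score was 4.96 ± 0.55 in soft and 5.58 ± 0.57 in stiff (difference 0.62, SE 0.17, permutation p = 0.00071, adjusted p = 0.0149). Preset camera and fry called the list macrophage too (adjusted p = 3.66e-05 and 0.0301), while adjusted p = 0.821 with an estimated correlation. Trem2, a lipid-sensing receptor, rose by 1.07 (SE 0.24), Msr1, the scavenger receptor A, by 1.15 (SE 0.27), Lyz2, the macrophage lysozyme, by 1.31 (SE 0.31) and Fcgr1 by 0.87 (SE 0.25), each in at least 17 of 21 stiff tumours relative to the soft median. Adgre1, which encodes F4/80, rose by 0.89 (adjusted p = 0.0171). The calls of C1qa and C1qb, the other 2, were not made in 17 and 2 of 43 fits with 1 tumour left out. Csf1r, Cd68 and Mrc1 had values of 0.48, 0.39 and 0.76 that did not pass (adjusted p = 0.111, 0.283 and 0.155). The difference was 0.76 in deep libraries (adjusted p = 0.03). For the list macrophage, the median over members, the adipocyte and muscle covariates and the covariate for the genes around Met ended the call (adjusted p = 0.0846, 0.135 and 0.0592).

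Other immune lists did not pass on the mean score over all tumours. With vessel and blood scores as covariates, chosen after seeing the data, the list alternative macrophage activation was called higher (adjusted p = 0.00663), as were the list monocyte recruitment, the list inflammatory macrophage activation and the list neutrophil (adjusted p = 0.0224, 0.0134 and 0.00144). Of 11 tested monocyte recruitment genes 4 rose, among them Ccl12, Csf1 and Cx3cr1 by 1.21, 1.15 and 0.86, while 1, Cx3cl1, fell by 0.90 (list adjusted p = 0.194). The rise of Ccl5 was 0.69 without stiff 31 (adjusted p = 0.12). Without soft 21 the Cx3cl1 value was -0.73 (adjusted p = 0.0553). Among alternative activation genes 2 of 5 rose (list adjusted p = 0.139, and 0.0233 on log2(TPM + 1)): Folr2 by 1.23 (0.93 without stiff 41, adjusted p = 0.102, and not called in 6 of 43 such fits) and Arg1, an arginase, by 1.17 (adjusted p = 0.0487, a call that 27 of 43 fits with 1 tumour left out did not make; in deep libraries 0.87, adjusted p = 0.279). Nos2, the inducible nitric oxide synthase, had a value of -0.51 (adjusted p = 0.399), and the inflammatory activation list did not pass (adjusted p = 0.433, 1 of 10 genes higher, Cd86 by 1.00, and none adjusted over the list alone). The Cd86 call was not made in 6 of 43 fits with 1 tumour left out. Neutrophil markers had a score difference of 0.88 (adjusted p = 0.139), and in deep libraries it was 0.42 (permutation adjusted p = 0.669). Without the globin-rich libraries the difference was 1.29 and passed (adjusted p = 0.0286). The list neutrophil also passed on log2(TPM + 1) (adjusted p = 0.0382) and with preset camera (adjusted p = 0.039), while adjusted p = 0.821 with an estimated correlation. Cxcr2 alone of the 6 tested neutrophil genes rose, by 1.36, but it is repeat-bearing and uncertain. Dendritic cell and MHC class II genes differed by 0.01 (SE 0.24). T and NK cell genes summed to 20.6 ± 12.8 CPM in soft and 24 ± 18 in stiff (permutation p = 0.656), and B and plasma cell genes to 8.9 ± 9 and 16.9 ± 45.2 CPM (p = 0.987). With medians of 64 and 20 counts per library and these spreads between tumours, small differences in the lymphocyte sums may have been missed.

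Skeletal muscle genes were higher in stiff tumours. Of 6 tested members of 12, 5 rose and 1 did not pass (6 rose adjusted over the list alone), and the score was 1.44 ± 1.55 in soft and 3.58 ± 2.43 in stiff (difference 2.13, SE 0.63, permutation p = 0.00126, adjusted p = 0.0176). Preset camera and fry called the list skeletal muscle too (adjusted p = 0.00155 and 0.0334), while adjusted p = 0.821 with an estimated correlation. Mylpf, a fast-fibre myosin light chain, rose from 6.81 ± 10.8 to 172 ± 419 CPM, and Tnni2, a fast-fibre troponin, from 3.43 to 46.6 CPM. Ckm, the muscle creatine kinase, and Mb, myoglobin, rose by 2.87 and 2.44 on the log2 scale. DESeq2 did not call Ckm (1.26, adjusted p = 0.136), nor did limma voom call Mb (0.61, adjusted p = 0.596). Without the globin-rich libraries the call of the list was lost (difference 1.96, adjusted p = 0.117). With the adipocyte and muscle covariates the values of Mb and Ckm turned to -0.89 and -0.47, neither called. Of 3 tested adipocyte genes, Slc2a4 and Fabp4 fell by 1.97 and 2.12, the latter in a call that 26 of 43 fits with 1 tumour left out did not make, with values from -3.56 to -1.87 (list adjusted p = 0.077).

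No list of lipid peroxidation, oxidant production or antioxidant genes passed. Among 13 tested lipid peroxidation drivers 2 rose and 2 fell over all genes, and 6 rose and 3 fell adjusted over the list alone (score difference 0.10, SE 0.08, adjusted p = 0.411). Ptgs1, cyclooxygenase 1, and Cyb5r1 rose by 1.03 and 0.62, while Alox12, a lipoxygenase, and Lpcat3, which places polyunsaturated chains in phospholipids, fell by 1.69 and 0.62. Acsl4, which activates polyunsaturated fatty acids, had a value of 0.93 (adjusted p = 0.0644 over all genes and 0.0245 over the list alone). Alox15 was too low to test, with 62 counts over all soft and 33 over all stiff libraries. Of 11 NADPH oxidase genes Ncf4 and Cyba rose by 0.79 and 0.71 (list adjusted p = 0.253), and Cybb had a value of 0.33 (adjusted p = 0.356). The Cyba call was lost without stiff 38 (0.61, adjusted p = 0.0572). Of 14 lipid peroxide defence genes Gch1 fell by 0.98 and Dhodh, which is repeat-bearing and uncertain, rose by 0.86 (list adjusted p = 0.433). Gpx4, the phospholipid hydroperoxidase, and Slc7a11, the cystine transporter, had values of 0.10 and -0.67 (adjusted p = 0.842 and 0.141). Nqo1 and Hmox1 had values of 0.11 and -0.88, and the NRF2 target list did not pass (adjusted p = 0.315), with Prdx1 higher by 0.52 in a call that 18 of 43 fits with 1 tumour left out did not make. Of 13 aldehyde detoxification genes, Adh5 and Aldh9a1 rose by 0.59 and 0.51 and Aldh1a1 fell by 2.08 (list adjusted p = 0.771). Aldh1a3, repeat-bearing and uncertain, rose by 1.73, and without stiff 38 its value was 0.80 (adjusted p = 0.186), and in deep libraries 0.04 (adjusted p = 0.966). Aldh2 was 347 CPM in soft and 341 in stiff. Plin2, a lipid droplet coat protein, and Acadl, a fatty acid dehydrogenase, rose by 0.98 and 0.71 within a fatty acid list that did not pass (adjusted p = 0.946). In deep libraries the calls of Ptgs1, Lpcat3, Gch1, Cyba and Aldh9a1 ended (adjusted p = 0.0644, 0.0837, 0.128, 0.125 and 0.0607).

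DNA damage and repair lists did not pass on the mean score over all tumours. With the vessel and blood covariates, the list base excision repair and the list nucleotide excision repair were called lower (adjusted p = 0.0299 and 0.0297). Of 16 DNA damage checkpoint genes 2 rose, Rad9a by 0.65 and Atrip, repeat-bearing and uncertain, by 1.73 (list difference 0.13, SE 0.08, adjusted p = 0.266). H2afx had a value of -0.05 (SE 0.25, adjusted p = 0.903). Of 15 base excision repair genes none passed over all genes or over the list alone (difference -0.03, SE 0.11, adjusted p = 0.859), and Ogg1, the 8-oxoguanine glycosylase, had a value of 0.13 (adjusted p = 0.708). Exo1, repeat-bearing and uncertain, rose by 0.64 in the homologous recombination list, which did not pass (adjusted p = 0.244). Ercc3 rose by 0.58 and Ercc4, repeat-bearing and uncertain, fell by 1.20 among nucleotide excision repair genes (adjusted p = 0.214). Mutagenic polymerases and cytidine deaminases had a difference of 0.06 (SE 0.13, adjusted p = 0.8). In these tumours from p53null tissue the p53 target list differed by -0.15 (SE 0.08, adjusted p = 0.194), Plk2 and Btg2 fell by 1.01 and 0.68, and Cdkn1a had a value of -0.16 (adjusted p = 0.778). The Btg2 call was lost without soft 17 (-0.59, adjusted p = 0.0542), and those of Btg2 and Exo1 in deep libraries (adjusted p = 0.0987 and 0.1).

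Lists tied to matrix mechanics did not pass on the mean score over all tumours, although single genes did. Of 20 YAP and TAZ targets 3 rose and 2 fell (3 and 4 adjusted over the list alone; score difference -0.08, SE 0.13, adjusted p = 0.771). Ankrd1, a strain-responsive nuclear and sarcomere protein that muscle also makes, rose by 2.27 (SE 0.45, adjusted p = 0.000778), while Ccn1 and Ccn2 had values of -0.19 and -0.55 (adjusted p = 0.7 and 0.169). The Amotl2 call was lost without stiff 41 (0.40, adjusted p = 0.121), and that of Axl was not made in 16 of 43 fits with 1 tumour left out. Igfbp3 and Arhgef17 fell by 2.16 and 0.84. The Igfbp3 value was -0.98 with limma voom (adjusted p = 0.15), -0.51 without the globin-rich libraries (adjusted p = 0.366), 0.28 with the adipocyte and muscle covariates and 0.17 with the vessel and blood covariates. Of 19 integrin adhesion and actomyosin genes 6 fell and none rose (difference -0.45, SE 0.15, adjusted p = 0.0569). The difference was -0.71 in deep libraries (permutation adjusted p = 0.0225) and -0.31 without the globin-rich libraries (permutation adjusted p = 0.229). Z-scores, preset camera and fry called this list lower (adjusted p = 0.0373, 0.00785 and 0.0334), while adjusted p = 0.821 with an estimated correlation. Itgb3, the beta-3 integrin, Pxn, paxillin, Flna, filamin A, and Ptk2, focal adhesion kinase, fell by 1.76, 0.84, 0.71 and 0.60, and Vcl had a value of -0.15 (adjusted p = 0.807). The calls of Myh9 and Actn4 were not made in 19 and 23 of 43 fits with 1 tumour left out. Interstitial matrix genes Col6a3, Sparc and Bgn fell by 1.61, 0.96 and 1.02 (list adjusted p = 0.264), and Col1a1 had a value of -0.23 (adjusted p = 0.733). The Sparc and Bgn calls were not made in 13 and 19 of 43 fits with 1 tumour left out. Of 14 crosslinking genes Tgm2 and Plod1 fell by 0.85 and 0.58 (list adjusted p = 0.315), the latter in a call that 26 of 43 fits with 1 tumour left out did not make, and Lox and Plod2 had values of -0.49 and -0.26 (adjusted p = 0.575 and 0.372). Among 13 matrix proteases Mmp3 and Mmp13 rose by 2.46 and 1.69 and Adamts4 and Mmp14 fell by 1.31 and 0.80 (list adjusted p = 0.244, and 4e-04, higher, with the vessel and blood covariates). Without stiff 41 the Mmp3 value was 0.81 (adjusted p = 0.219), and DESeq2 did not call it (adjusted p = 0.172). DESeq2 called Lox higher (1.03, adjusted p = 0.0344). With 1 tumour left out, the edgeR value of Lox ran from -0.87 to 1.015, turning its sign in 1 of 43 fits. In deep libraries the calls of Flna and Sparc ended (adjusted p = 0.0779 and 0.105). Without the globin-rich libraries those of Arhgef17, Col6a3, Sparc, Bgn, Plod1, Ptk2, Adamts4 and Mmp14 ended.

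No epithelial list passed on the mean score over all tumours. With the vessel and blood covariates, epithelial junction genes were called lower and mesenchymal transition factors higher (adjusted p = 0.00144 each). Luminal and milk genes differed by -0.08 (SE 0.42, adjusted p = 0.904), with Cited1, Prlr and Foxa1 falling by 3.12, 1.67 and 2.21. Without soft 9 the Prlr value was -1.21 (adjusted p = 0.0662), and without soft 16 the Foxa1 value was -1.94 (adjusted p = 0.0562, 1 of 3 such fits). In deep libraries the calls of Cited1, Prlr, Foxa1, Krt19 and Krt15 ended (adjusted p = 0.245, 0.306, 0.351, 0.126 and 0.26). Krt19 fell by 2.50 among junction genes (list adjusted p = 0.805). The basal keratin Krt15 had a called value of -2.82 that was -0.36 (adjusted p = 0.745) without soft 11. Proliferation genes Pcna and Ccnb1 rose by 0.45 and 0.58 (list difference 0.24, SE 0.12, adjusted p = 0.187, against 0.039 with preset camera and adjusted p = 0.821 with an estimated correlation), and Mki67 had a value of -0.01. Fibroblast, TGF-beta response, hypoxia and glycolysis, and type I interferon lists gave adjusted p-values of 0.807, 0.602, 0.946 and 0.744. Lists of nuclear-encoded oxidative phosphorylation, mesenchymal transition factors, and cholesterol and fatty acid synthesis gave 0.315, 0.558 and 0.805, and basal epithelium 0.805. The list of tissue handling stress differed by -0.31 (adjusted p = 0.187) and that of the mitochondrial genome by -0.15 (adjusted p = 0.433).

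Across the 43 tumours, 1 of 9 relations with the macrophage score passed. NADPH oxidase genes, several of which are made by phagocytes, rose with the macrophage score (r = 0.66, permutation p = 1e-05, adjusted p = 9e-05, the p being the smallest possible; rho = 0.67, p = 1e-05). Without stiff 41 and soft 11, the tumours farthest from the median macrophage score, r was 0.61 (p = 3e-05). In deep libraries r was 0.67 (adjusted p = 0.00072). Within soft r was 0.79 (adjusted p = 0.00018), and within stiff it was 0.44 (permutation p = 0.0451, adjusted p = 0.135). Lipid peroxidation drivers gave r = 0.30 (p = 0.0535, adjusted p = 0.12; rho = 0.29, p = 0.0649), base excision repair -0.36 (p = 0.0192, adjusted p = 0.0575; rho = -0.38, p = 0.0131) and interstitial matrix 0.38 (p = 0.0135, adjusted p = 0.0575; rho = 0.37, p = 0.0139). By rho the last 2 passed (permutation adjusted p = 0.0417 each). Neither passed by rho without stiff 41 and soft 11 (adjusted p = 0.121 and 0.169) or in deep libraries (adjusted p = 0.195 each). Base excision repair turned to r = 0.165 on log2(TPM + 1) (adjusted p = 0.288). On log2(TPM + 1) 6 relations passed, lipid peroxidation drivers among them (r = 0.58, adjusted p = 0.00027).

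Of the 9 relations, 2 differed between soft and stiff tumours, those of the DNA damage checkpoint and aldehyde detoxification. Differences for NADPH oxidase, base excision repair and interstitial matrix did not pass (adjusted p = 0.144, 0.144 and 0.512). In stiff tumours the DNA damage checkpoint score was lower where the macrophage score was higher (r = -0.74, permutation p = 8e-05, adjusted p = 0.00072; rho = -0.76, p = 0.00012; 19 tumours without stiff 31 and stiff 41, r = -0.62, p = 0.00447), and in the 10 deep stiff libraries r was -0.81 (p = 0.00391). In soft tumours r was 0.05 (p = 0.844), and the difference between groups passed when group labels were permuted over centred scores (adjusted p = 0.0369). On log2(TPM + 1), chosen after seeing the data for these within-group values, r within stiff was -0.16 (adjusted p = 0.58). In soft tumours 5 relations passed: NADPH oxidase, interstitial matrix (r = 0.68, adjusted p = 0.00195), base excision repair (r = -0.53, adjusted p = 0.0189, and on TPM 0.199, adjusted p = 0.425) and the following. Aldehyde detoxification gave r = -0.67 (adjusted p = 0.00195; rho = -0.69, p = 0.00049; 20 tumours without soft 11 and soft 22, r = -0.61, p = 0.00416), against 0.27 in stiff (difference adjusted p = 0.0018). Within the soft sets of high and low endothelial score it was 0.35 (9 tumours) and -0.75 (13 tumours), and on TPM within soft it was 0.12 (adjusted p = 0.593). Lipid peroxidation drivers gave r = 0.59 (p = 0.00483; rho = 0.39, p = 0.0723), which rested on soft 11 and soft 22: without them r was 0.33 (p = 0.165). Within the soft sets of high and low endothelial score r was 0.27 (9 tumours) and 0.92 (13 tumours, permutation p = 7e-05). In the set of 13 rho was 0.71 (permutation p = 0.00848). This set holds both soft 11 and soft 22, so its value is not separate support. For that list the difference between groups did not pass (adjusted p = 0.106).

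**Figure D3:**
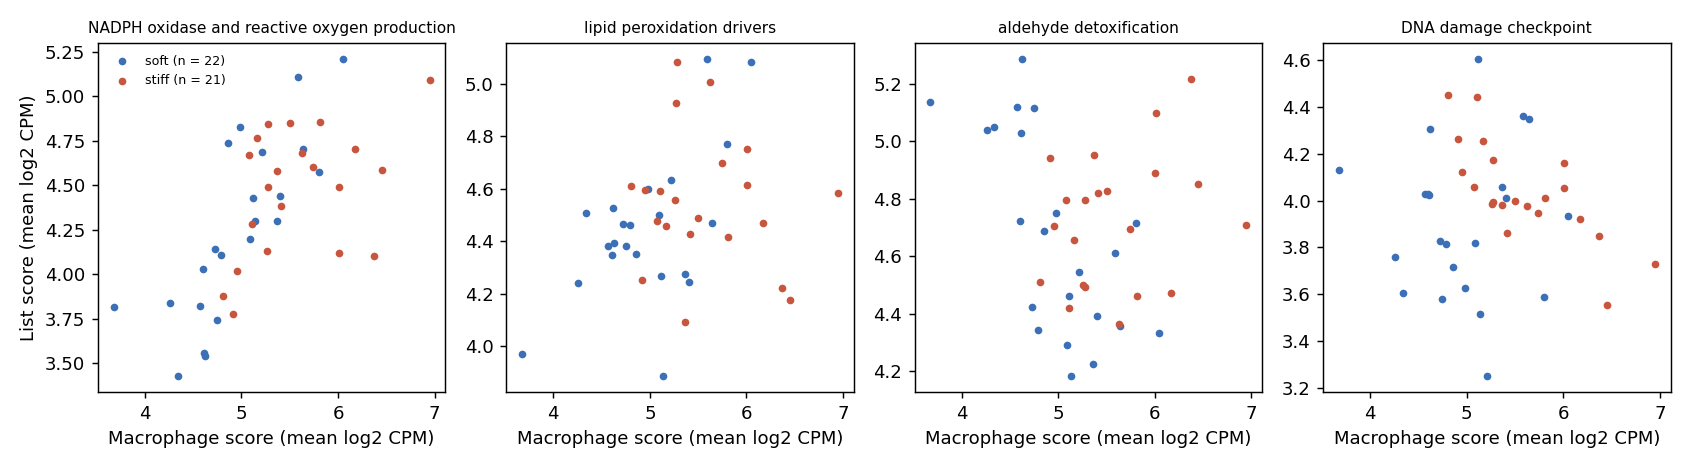
Scores (mean log2 CPM) of 4 lists on the vertical axes against the macrophage score on the horizontal axes, 1 point per tumour, with soft and stiff in different colours. The NADPH oxidase score rises with the macrophage score (r = 0.66 over 43 tumours), and the DNA damage checkpoint score falls with it among stiff tumours (r = -0.74).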

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

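All alternatives listed here were set before the data were examined, except those named as chosen after seeing the data. No paired analysis was possible because the groups share no replicate numbers. At these depths, genes lowered by 1 on the log2 scale were recovered less often than genes raised by 1 in simulated counts (50% and 78%). For genes higher and lower in stiff (955 and 1205), the other scalings, filters, count tests, length offsets, depth settings and the surrogate variable stayed within 1.5 times. Counts outside that were 584 and 283 on log2(TPM + 1), 558 and 278 on log2(TPM + 0.1), and 134 and 262 with adipocyte and muscle covariates. Chosen after seeing the data, the Met neighbourhood covariate gave 352 and 278. The cause was not tested. Over all these settings 1 gene called lower was called higher in another setting, with the endothelium and red blood cell covariates. With each tumour left out, genes higher in stiff ranged from 821 to 1176 and genes lower in stiff from 942 to 1368.

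Lists higher and lower in stiff (2 and 1) became 3 lower with z-scores, 1 higher with medians, 4 higher on log2(TPM + 1), 2 lower without shallow libraries, 0 and 0 with adipocyte and muscle covariates, 4 and 5 with camera's preset correlation, 0 and 0 with its estimated correlation and 4 lower with fry. Chosen after seeing the data, vessel and blood covariates gave 8 and 4, and the Met covariate 1 and 0. With each tumour left out lower lists ranged from 1 to 5, with basement membrane, macrophage and skeletal muscle called in all 43 fits. The count was 5 without soft 4, soft 12, soft 22 or stiff 25, 4 without stiff 34 and 3 without soft 18. It was 2 without soft 3, 11, 16 or 20 or stiff 28, 31, 33 or 41.

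Relations with the macrophage score (1 of 9) became 3 with centred scores, 5 within soft, 2 with z-scores, 6 on log2(TPM + 1) and 5 with adipocyte and muscle scores regressed out. On TPM within groups, chosen after seeing the data, 5 passed in soft and 4 in stiff. Pooled signs turned on TPM for 5 relations: the DNA damage checkpoint (r from -0.10 to 0.38) and NRF2 targets (from -0.001 to 0.35), which passed there, and base excision repair (from -0.36 to 0.165), aldehyde detoxification (from -0.21 to 0.26) and lipid peroxide defence (from -0.13 to 0.20), which did not. Within groups the TPM values were 0.57 for the checkpoint in soft and 0.55 for NRF2 targets in stiff, where r was positive on log2 CPM as well (0.05 and 0.37). All pooled values of r were higher on TPM, which was used without the TMM scaling of log2 CPM. The cause was not tested.

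Among named genes, signs turned as follows, with log2 values. DESeq2 called Lox at 1.03. With adipocyte and muscle covariates no longer called values were 0.18 for Fabp4, 0.007 for Lama4, 0.17 for Emcn, 0.044 for Pfkfb3, 0.23 for Ankrd37, 0.057 for Adamts4, 0.054 for Rgs5, 0.20 for Abcc9 (repeat-bearing and uncertain), -0.89 for Mb, -0.47 for Ckm, 0.16 for Rsad2 and 0.28 for Igfbp3. With the vessel and blood covariates they were 0.49 for Fabp4, 0.22 for Nid2, 0.14 for Tek, 0.25 for Cldn5, 0.31 for Cdh5, 0.029 for Kdr, 0.61 for Emcn, 0.14 for Sparc, 0.18 for Adamts4, 0.11 for Rgs5, 0.11 for Abcc9, 0.11 for Hbb-bt, 0.021 for Hba-a2, 0.084 for Hba-a1, 0.25 for Hbb-bs, 0.10 for Rsad2 and 0.17 for Igfbp3, and Egfl7 was called at 0.63. These covariates hold some of the same genes, and the groups differ in the muscle, vessel and blood genes, so they also remove group differences. Limma voom ended, without turning the sign, the calls of Igfbp3, Slc2a4, Fabp4, Aldh1a3, Folr2, Krt15, Krt19, Erg, Tek, Sparc, Cyb5r1, Gch1, Cited1, Prlr, Foxa1, Mmp3, Adamts4, Csf1, Btg2, Ccnb1, Exo1, Cyba, Arg1, Mb and the 4 globin genes. DESeq2 ended those of Aldh1a3, Mmp3 and Ckm. Uncalled values that changed sign without being called numbered 78 for named genes, 37 for lists and 15 for relations. Of the 24 genes named by lowest p, 6 lost their call with the adipocyte and muscle covariates. Those tested stayed called in the other settings for genes: 20 were tested at a mean CPM of at least 5 and 18 without repeat-bearing genes.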

Other observations

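Chosen after the result was seen were the chromosome and window scans, the look at single splits, the test of a gain around Met and that of depth for basement membrane genes. Chromosome 3 genes were higher in stiff tumours as a whole. The median deviation of its 326 well-expressed genes (mean log2 CPM of at least 4), relative to all such genes, was -0.12 ± 0.16 in soft and 0.15 ± 0.18 in stiff (SD; difference 0.26, permutation p = 2e-05, adjusted over 20 chromosomes 4e-04). It lay above the soft median in 20 of 21 stiff tumours, and the difference was 0.29 in deep libraries (p = 4e-05). Of 592 tested genes on this chromosome, S100a4 among them, 121 were called higher and 26 lower. No other chromosome passed, chromosome 9 being next (difference -0.11, adjusted p = 0.147).

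Some tumours had short stretches of neighbouring genes far above the other tumours. Median deviations over 10 neighbouring genes reached 3.59 in soft 17, 2.86 in soft 13 and 2.78 in soft 10 on chromosome 16 (17280351 to 17911348, Pi4ka to Ess2), 3.54 in stiff 41 on chromosome 9 (3403592 to 9239101, with Yap1, Mmp3 and Mmp12), 3.35 in soft 6 and 3.06 in stiff 30 on chromosome 6 (17065149 to 24528013, the window that begins at Tes next to Met), and 3.03 in soft 3 on chromosome 8 (13338751 to 22071627). The chromosome 16 window was also the highest in soft 5 (2.37) and soft 2 (1.97), and in no stiff tumour, and the labels do not say whether these tumours share a donor. Soft 2, 5, 10, 13 and 17 all lie in the soft set of high endothelial score (6.65 to 8.01). Whether the vessel difference rests on related tumours therefore cannot be told. Soft 10 and soft 13 were also the closest pair of libraries. Soft 14 and 15 (r = 0.960) shared their highest window, on chromosome 8 (13077189 to 13799193, 2.32 and 2.18). So did soft 4 and 12 (r = 0.947), on chromosome 6 (17692933 to 29216364, 2.52 and 2.16). The close pairs stiff 36 and 37 (r = 0.958) and soft 1 and 14 (r = 0.943) did not. If such tumours are related, the p-values given here treat related tumours as independent. Calls of Mmp3, Amotl2 and Folr2 were among those lost without stiff 41. As a test of groups, 10 of 1294 windows passed, and shuffled gene orders gave a median of 9.5 and up to 16. Of the 10 windows 6 lay on chromosome 3, all higher in stiff, 3 on chromosome 9 and 1 on chromosome 2, all lower. The shuffled orders bear on the total count and not on this placement.

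The counts of 955 higher and 1205 lower genes were set against 99 random splits of the same tumours. Of the 100 splits, the real one included, 2 gave at least 955 calls in 1 direction and 1 gave at least 1205. Counts as high as the real ones were therefore rare, at a share under 0.05, if the tumours are exchangeable. Donor and batch are not labelled, so groups of related tumours are not covered by this test. Of the other splits 26 gave at least 1 call. The highest of the other splits was 984, and the next 37. That split called 984 and 723 genes, and its groups parted most, by t, in adipocyte (difference 1.36), pericyte (1.32) and collagen crosslinking (0.60) scores, read from that split alone. A split with so many calls points to a structure of the tumours, which was not tested further. Within stiff tumours, 10 deep against 11 shallow libraries gave 0 calls in either direction with edgeR, with 902 of 9934 genes at an unadjusted p under 0.05; no other tool was run on this split.

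Genes next to Met on chromosome 6, chosen after their values were seen, were higher in stiff tumours: Tes (17065149 to 17105828), Cav2, Capza2 and St7 rose by 2.90, 2.00, 2.17 and 1.92, while Met (17463800 to 17573980) had an edgeR value of 1.47 (adjusted p = 0.112) and a difference in mean log2 CPM of 2.89 (permutation p = 0.00015). The median deviation of 7 neighbours within 1 Mb exceeded that of 26 genes 3 to 10 Mb away by 1.18 more in stiff than in soft (permutation p = 0.00016). None of the 10 windows that passed the scan of groups lay on chromosome 6. The value of 1.18 also holds the distant genes of soft 4, 6, 12 and 22, which have high Met (7.90, 9.29, 7.39 and 9.59 log2 CPM). Their distant genes (1.17, 1.93, 1.13 and 1.84) lay above their neighbours (-1.04, 1.30, -0.10 and 1.02). Epithelial or mesenchymal makeup is argued against, since with these scores as covariates the neighbourhood difference was 1.27 (SE 0.30, p = 1e-04) against 1.24 without. A gain of the segment in part of the tumours may account for this, as a hypothesis. Neighbours lay more than 1 above the soft median in 12 of 21 stiff and 3 of 22 soft tumours, which does not count gains. Soft 5, stiff 33 and stiff 41 are in that count with lower Met (4.04, 5.18 and 4.96 log2 CPM). Stiff 23, 26 and 28, with Met at 9.47, 7.08 and 8.88, are not, their neighbours lying at -0.67, -0.7 and -1.08. Nor are soft 4 and soft 12. A difference in donor tissue between groups stays open because the labels give no donor. DNA was not analysed here. The depth gap as the whole source is argued against by the deep-library difference of 1.15 (SE 0.56, p = 0.0142), but as a part it cannot be told apart, since with 10 stiff tumours 1.15 passes 50% of 1.24 by less than its standard error.

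Repeat-bearing genes made up 16.7% of genes higher in stiff (159 of 953), 7.8% of genes lower and 8.2% of uncalled genes (odds ratio 2.25 against uncalled, Fisher's exact p = 8.97e-16). The share of counts on annotated retained-intron transcripts differed by -0.041 percentage points (6.25% ± 1.04 in soft, 6.21% ± 0.53 in stiff, permutation p = 0.876). Reads from introns outside annotated transcripts are not counted, so this does not decide whether stiff libraries held more unspliced RNA. In deep libraries the 159 genes kept a median log2 fold change of 0.95, against 0.88 in all libraries. They were chosen in all libraries, which include the deep ones, and the raised share was not recomputed there. Depth as a source of these calls therefore stays open. Reads shared through the repeats may account for part of these calls: within groups the 159 genes had a mean pairwise correlation of 0.275, above the 0.168 of random sets of other genes called higher (highest 0.233, one-sided p = 1e-04, the smallest possible). Whether stiff tumours transcribe more of such repeats stays open and was not tested.

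Basement membrane genes had a score difference of -0.86 between stiff and soft. The depth gap is argued against, since the difference was -1.27 without shallow libraries (p = 5e-05). With endothelium, pericyte and red blood cell scores as covariates it was -0.47 (SE 0.16, p = 0.00508), so vessel content may account for part of it. Vessel content as the main source cannot be told apart from a change in other cells, because -0.47 lies within its standard error of 50% of the unadjusted difference. The matrix stiffness itself, which cannot be told apart here from other effects of the ribose treatment, stays among the open explanations.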
